A study of Mus musculus with 9 samples.

How the data were processed

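Polyadenylated RNA from 9 samples of FVB/N mouse skeletal muscle myoblasts was compared, 3 each of the parental population (PAR), FRCs of cycle 1 (FRC1) and SRCs of cycle 3 (SRC3). Per the labels' protocols, RNA was extracted with a DNase step, libraries followed a stranded TruSeq mRNA protocol, and single reads of 50 nt were run on a HiSeq 2500. The deposited files hold whole-number read counts per gene for each library, which the authors had not normalized. The submitters' processing notes name HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 and the mouse build GRCm38. Their settings, including the strand setting of the counting, are not given in the sources used here. Without that setting, reads of overlapping or antisense genes cannot be told apart. Reads with several alignments were tallied apart from gene counts, so genes with near-identical copies, such as those of ribosomal proteins, actins, fast myosins, mitochondrial proteins and class I antigens, were counted from their unique reads only and are uncertain.

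Each file ends with 5 summary lines that name no gene, and these stayed out of library sizes and tests. Of the uniquely aligned reads, 5.923 to 7.917% lay in no gene and 1.175 to 1.214% were ambiguous between genes. Gene counts came to 13012996 to 14336279 per library. The files list 47729 genes, of which 47224 were matched by identifier to GENCODE M21, the annotation given here for GRCm38, for symbols and locations, and 505 were not. Of the tested genes 12515 had a location. The share of counts in the 10 most abundant genes averaged 4.12% in PAR, 4.25% in FRC1 and 4.39% in SRC3. Replicates were compared before averaging. The chi-square statistic per degree of freedom of their counts over genes was 1.87 to 7.97, so that no pair differed by as little as sampling noise.

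Groups were taken from the sample titles. Genes with enough counts were kept with filterByExpr of edgeR 4.0.16 at its defaults (a count of 10 in a library and 15 in total, scaled to depth), which left 12540, in R 4.3.3. TMM factors lay within 1.2% of 1. Counts of all 9 libraries were fitted in a single model with the group as its term and 6 residual degrees of freedom, and each pair of groups was compared with a two-sided quasi-likelihood test with robust dispersion (glmQLFit and glmQLFTest). The Benjamini-Hochberg adjusted p threshold was 0.05. The common biological coefficient of variation was 0.0535. Fold changes against groups with 0 counts are bounds against 3 counts over the group. With 1 to 3 counts, the ratio of counts is given with its 95% interval. Floors and intervals cover counting error only, since the reads carry no molecular identifiers. Log2 CPM for principal components and gene lists used a prior count of 2.

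Of 34 gene lists, 30 had at least 5 tested members and were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01. It compares a list with the other genes. Camera called 12 lists in FRC1 against PAR (5 higher, 7 lower), 5 in SRC3 against PAR (2 and 3) and 5 in SRC3 against FRC1 (3 and 2). With a correlation estimated for each list it called 0 in every comparison, with lowest adjusted p of 0.29, 0.49 and 0.45. Fry, which tests whether a list moves in one direction on balance without comparing it with other genes, called 16, 15 and 17 lists.

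The genes named in the text followed a rule. For each comparison it took the 8 largest rises and 8 largest falls among genes that passed, with groups that did not overlap, at least 5 CPM in the higher group and a symbol that was not a predicted or clone name. It added up to 4 members with the largest changes in each described list, among those that passed with at least 1 CPM in the higher group, and 10 myogenic and proliferation genes in every comparison. Members that did not pass are given by value. The design, the lists, the naming rule and the alternatives were set before the data were examined.

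The pipeline was tested on simulated data, drawn from the means and library sizes of the real libraries with 200 changed genes, 50 for each fold size. For FRC1 against PAR it recovered 86, 82 and 100% of genes changed 1.5-, 2- and 4-fold and 42% at the smallest fold size, below 1.5-fold, and called 11 of 12340 unchanged genes. For SRC3 against PAR it recovered 84, 90 and 98%, and 56% at the smallest, and called 11. For SRC3 against FRC1 it recovered 78, 92 and 98%, and 44% at the smallest, and called 14. In the simulated SRC3 against PAR, a list of 20 genes shifted 1.5-fold was called and 0 unshifted lists were. Genes were drawn independently of each other, so the simulation does not show how the list test behaves when members vary together. Only 200 of 12540 genes were changed, against 28.3 to 37.9% called in the real comparisons, so recovery and false calls there may differ.

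Alternatives were another normalization (RLE size factors or library sizes alone), no filter or a stricter filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a fit of only the groups compared, the replicate number as a block, a test against a 2-fold change, and leaving out each library in turn. For shared controls, 20 simulations drew all 9 libraries at the PAR levels, so that unchanged groups shared simulated PAR libraries.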

Results

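Messenger RNA was sequenced from cultured myoblasts, the proliferating precursors of skeletal muscle fibres, of the inbred mouse strain FVB/N. The labels named 3 populations, with 3 libraries each and 9 in all: the parental cells (PAR) and 2 reserve cell populations, FRCs of cycle 1 (FRC1) and SRCs of cycle 3 (SRC3). Reserve cells are the undifferentiated mononucleated cells that persist when a myoblast culture is induced to form myotubes. Per the labels, the reserve populations were grown under proliferation conditions and passaged between isolation and harvest, and every RNA sample had a RIN of 10. The libraries held 14336279, 13134823 and 14165532 gene counts in PAR, 13152535, 14312598 and 14022307 in FRC1, and 13617108, 13059602 and 13012996 in SRC3. At these depths 3 counts in 1 library corresponded to 0.21 to 0.231 CPM, the level of a gene relative to all gene counts of its library. Between 17071 and 17416 genes had at least 1 read in a library, and 12540 genes were tested. CPM are scaled by TMM, and values are means ± SD (n = 3 per group). Unless a test is named otherwise, adjusted p for genes came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and adjusted p for gene lists from limma's camera.

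The SRC3 libraries stood apart from the other 6 libraries in the expression of the 12540 genes. Their scores on the first principal component, which held 59.3% of the variance, lay between 42.08 and 45.08, against -23.65 to -19.21 for PAR and FRC1. PAR and FRC1 separated on the second component, which held 21.6% of the variance. PAR lay between 21.35 and 22.19 there and FRC1 between -28.2 and -15.44, with FRC1 replicate 1 nearest to PAR. Correlations of log2 CPM across genes, which are not independent replicates, were 0.991 to 0.995 within groups, 0.98 to 0.987 between PAR and FRC1, 0.964 to 0.966 between PAR and SRC3, and 0.963 to 0.969 between FRC1 and SRC3. The labels do not say that the replicates came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

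**Figure D1:**
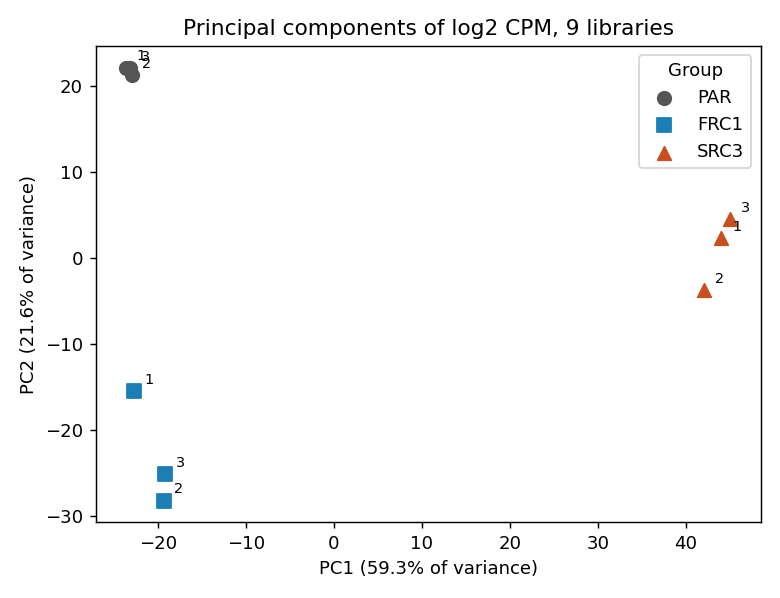
Scores of the 9 libraries on principal components 1 and 2 of log2 CPM, coloured and shaped by group and numbered by replicate. The 3 SRC3 libraries lie between 42.08 and 45.08 on component 1, and component 2 separates PAR (21.35 to 22.19) from FRC1 (-28.2 to -15.44).

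The comparison of FRC1 with PAR asked how reserve cells of cycle 1, kept under proliferation conditions, differed from the parental cells. The muscle differentiation genes Myog, Acta1 and Myl1, which were barely detected in PAR, were higher in FRC1, as was the immediate early gene Fosb. The cell cycle inhibitor genes Cdkn2a and Cdkn2b, the p53 target Trp53inp1 and the respiratory chain gene Ndufs1 were lower. Myog, which encodes the differentiation factor myogenin (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548, GRCm38), rose 15.3-fold from 0.574 ± 0.194 to 8.97 ± 1.58 CPM (log2 fold change 3.94, SE 0.27; edgeR adjusted p = 7.2e-09). Acta1, the skeletal muscle actin gene (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), rose 25.8-fold from 1.33 ± 0.293 to 34.45 ± 3.29 CPM (log2 fold change 4.69, SE 0.41; edgeR adjusted p = 0.00013). Cdkn2a and Cdkn2b, neighbouring genes for cell cycle inhibitors, fell 1.86-fold and 1.76-fold. The myoblast factor Myod1 stood at 771 ± 15.9 CPM in FRC1 and 776.5 ± 15.1 in PAR (edgeR adjusted p = 0.88).

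Of the 36 tested sarcomere and contractile genes, 27 rose, 7 fell and 2 did not pass; adjusted over the list alone, 28 rose and 7 fell. The list was called higher in FRC1 (camera adjusted p = 3.1e-10; adjusted p = 0.29 with an estimated correlation). Myl1, a myosin light chain gene, rose 75.3-fold to 7.96 ± 0.625 CPM (log2 fold change 6.23, SE 0.46) and the perinatal myosin gene Myh8 52.1-fold to 6.74 ± 1.08 CPM (log2 fold change 5.7, SE 0.62). Myh7, the slow myosin heavy chain gene, had 440 counts over the 3 FRC1 libraries and 1 over PAR, a ratio with a 95% counting interval of 78.4 to 17400. Tnnc2, a troponin gene, had 164 counts against 3, with an interval of 18.3 to 267. Without PAR replicate 3, which held the 1 PAR read, Myh7 was at least 96.6-fold higher, and without PAR replicate 1 the interval of Tnnc2 was 19 to 4260. All 26 tested members below 5 CPM in PAR rose, and the summed level of the 26 went from 21.1 to 217 CPM. Of the 26, 13 reached the count filter through FRC1, which favours a rise, as does choosing members by a low PAR level. These 13 also enter the counts and the camera result of the list. The 13 that passed the filter without FRC1 all had a positive log2 fold change. Among the 10 members at or above 5 CPM in PAR 1 rose and 7 fell. Des, the desmin gene, was among the 7 and went from 731 ± 17.1 to 620.9 ± 24.6 CPM. The summed level of the whole list was 1962 CPM in PAR and 2030 in FRC1. Such intervals cover counting error only.

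Among the 17 tested myogenic regulators and fusion genes 3 rose, 9 fell and 5 did not pass (3 and 10 adjusted over the list alone). The list was not called (camera adjusted p = 0.057), and its median log2 fold change of -0.25 and the direction of the test, lower in FRC1, were opposite in sign to its mean of 0.50. The 3 that rose were Myog, Mef2c, another muscle transcription factor gene, 12.9-fold to 6.64 ± 0.433 CPM, and Mybph, a myosin binding protein gene, 51.4-fold to 12.84 ± 1.89 CPM. Rb1, which encodes the retinoblastoma protein, fell 1.62-fold to 12.87 ± 2.16 CPM (log2 fold change -0.69, SE 0.12). The fusion genes Tmem8c (myomaker) and Gm7325 (myomixer) had log2 fold changes of -0.5 (edgeR adjusted p = 0.062) and -0.7 (edgeR adjusted p = 0.13). Myf5 had 0 reads in PAR and FRC1.

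Satellite cell and quiescence markers, 22 of which were tested, were called lower (1 rose, 7 fell, 14 did not pass, and 1 and 9 adjusted over the list alone; camera adjusted p = 0.021; adjusted p = 0.55 with an estimated correlation). Vcam1, an adhesion receptor gene, fell 1.62-fold from 214.5 ± 2.4 to 132.6 ± 25.2 CPM, and the growth factor receptor gene Fgfr4 fell 1.66-fold from 26.54 ± 2.21 to 16.04 ± 3.77 CPM. Gas1 fell 1.59-fold to 16.36 ± 4.61 CPM. Pax7, the satellite cell transcription factor gene, stood at 113.8 ± 7.55 against 127.1 ± 8.24 CPM (edgeR adjusted p = 0.053), and passed without FRC1 replicate 1 (0.018), PAR replicate 2 (0.037), SRC3 replicate 2 (0.033) or SRC3 replicate 3 (0.044), with a range of 0.018 to 0.26 over the 9 libraries left out in turn. Pax7 also passed with RLE size factors (edgeR adjusted p = 0.049), no filter (0.033) and a fit of the 2 groups alone (0.035). Pax3 (edgeR adjusted p = 0.36), Cd34 (0.12), Id1 (0.18) and Notch3 (0.32) did not pass, though Notch3 did without FRC1 replicate 1 (0.00013; range 0.00013 to 0.65).

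The proliferation marker Mki67 stood at 273.5 ± 19.6 CPM in FRC1 and 262 ± 15.8 in PAR (edgeR adjusted p = 0.72). Of 19 tested cell cycle inhibitors and pocket protein genes 2 rose, 7 fell and 10 did not pass (2 and 7 adjusted over the list alone; camera adjusted p = 0.02; adjusted p = 0.29 with an estimated correlation). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) went from 156.5 ± 0.183 to 84 ± 13 CPM (log2 fold change -0.9, SE 0.081; edgeR adjusted p = 1.3e-06). Cdkn2b (ENSMUSG00000073802, chromosome 4, 89306299 to 89311039) went from 89.55 ± 2.78 to 51 ± 8.12 CPM (log2 fold change -0.81, SE 0.098; edgeR adjusted p = 3.2e-05). Of 23 tested p53 targets 0 rose, 11 fell and 12 did not pass (0 and 12 adjusted over the list alone; camera adjusted p = 9.6e-06; adjusted p = 0.29 with an estimated correlation). Trp53inp1 fell 2.99-fold to 5.23 ± 0.166 CPM, Eda2r 1.96-fold to 14.75 ± 2.96 CPM, and Cdkn1a, the p21 gene, 1.39-fold to 104.3 ± 3.47 CPM.

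Immediate early genes, which respond quickly to growth factors and stress, were called higher: of 24 tested 12 rose, 0 fell and 12 did not pass, and 15 and 0 did so adjusted over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.29 with an estimated correlation). Fosb rose 3.18-fold to 4.14 ± 0.991 CPM, Nr4a1 2.1-fold to 11.79 ± 0.95 CPM and Nr4a2 1.66-fold to 54.13 ± 7.77 CPM. Among 28 genes of the unfolded protein and integrated stress response 13 rose, 6 fell and 9 did not pass, with 14 and 6 adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.6 with an estimated correlation). The endoplasmic reticulum genes Sdf2l1, at 210.9 ± 12.9 CPM, and Creld2, at 200.5 ± 7.92 CPM, rose 2.43-fold and 2.33-fold, and the lipoprotein receptor gene Vldlr fell 2.17-fold to 13.36 ± 0.235 CPM. This list was no longer called without PAR replicate 3 (camera adjusted p = 0.064; range 0.01 to 0.064).

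Of 42 nuclear genes of oxidative phosphorylation 0 rose, 17 fell and 25 did not pass (0 and 20 adjusted over the list alone; camera adjusted p = 0.00017; adjusted p = 0.36 with an estimated correlation), such as Ndufs1, 1.22-fold to 204.9 ± 4.91 CPM, and Atp5a1, 1.2-fold to 1359 ± 65.3 CPM. Of 10 mitochondrially encoded genes 0 rose, 5 fell and 5 did not pass (0 and 6 adjusted over the list alone; camera adjusted p = 0.0015; adjusted p = 0.5 with an estimated correlation); mt-Cytb fell 1.22-fold to 2615 ± 111 CPM and mt-Nd5 1.43-fold to 1011 ± 139 CPM. Of 29 glutathione genes and NRF2 targets 0 rose, 10 fell and 19 did not pass (0 and 10 adjusted over the list alone; camera adjusted p = 0.0072; adjusted p = 0.29 with an estimated correlation), among them Gstm1, 1.73-fold to 22.34 ± 1.43 CPM, and Hmox1, 1.44-fold to 52.09 ± 6.92 CPM. Ppargc1a, the gene of a regulator of mitochondrial biogenesis, fell 3.46-fold to 2.41 ± 0.164 CPM. Cytosolic ribosomal protein genes were called higher, with 20 of 75 up, 0 down and 55 not passing (19 and 0 adjusted over the list alone; camera adjusted p = 0.00023; adjusted p = 0.6 with an estimated correlation; fry adjusted p = 0.08, a lost call), as in Rpl13a, 1.19-fold to 826.1 ± 41.4 CPM. Mitochondrial and ribosomal protein genes have near-identical copies elsewhere in the genome, and reads with several alignments were set aside by the submitters, so their levels are uncertain.

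Imprinted genes were called lower, with 1 of 15 up, 9 down and 5 not passing, and the same counts of 1 and 9 adjusted over the list alone (camera adjusted p = 0.00083; adjusted p = 0.29 with an estimated correlation). The non-coding RNA gene H19 fell 1.49-fold from 1055 ± 34.9 to 710.2 ± 121 CPM and the receptor gene Igf2r 1.44-fold to 88.33 ± 8.65 CPM, while Igf2, the growth factor gene beside H19, rose 2.74-fold from 0.792 ± 0.161 to 2.2 ± 0.395 CPM. Glial and neural markers were called at the threshold, with 3 of 7 up, 0 down and 4 not passing (4 and 0 adjusted over the list alone; camera adjusted p = 0.04964; adjusted p = 0.29 with an estimated correlation). Tubb3 rose 3.36-fold to 38.16 ± 13.7 CPM and Ncam1, also present on myoblasts, 1.19-fold to 229.4 ± 17.8 CPM. That call was lost without PAR replicate 2 (camera adjusted p = 0.073), FRC1 replicate 2 (0.055), FRC1 replicate 3 (0.065), SRC3 replicate 1 (0.052) or SRC3 replicate 2 (0.05), and with library sizes alone (0.053) or a stricter filter (0.11), with a range of 0.039 to 0.073 over left-out libraries. Pericyte and smooth muscle markers were not called (5 of 9 up, 3 down; 5 and 3 adjusted over the list alone; camera adjusted p = 0.46), yet Acta2, the smooth muscle actin gene, rose 2.97-fold to 199.4 ± 30.4 CPM and the proteoglycan gene Cspg4 11.1-fold to 7.82 ± 2.91 CPM.

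Other large differences included Car3, a carbonic anhydrase gene, which rose 30.9-fold to 9.21 ± 0.619 CPM (59.3-fold without PAR replicate 3), and the cytokine gene Il11, which rose 5.01-fold to 14.14 ± 2.47 CPM. The largest falls by the naming rule were in Cd28, 6.86-fold to 1.12 ± 0.375 CPM, and in the cytokine gene Il33, 6.57-fold from 49.34 ± 1.11 to 7.61 ± 5.06 CPM (log2 fold change -2.72, SE 0.33; edgeR adjusted p = 0.0011; 10.5-fold without FRC1 replicate 1). In all, 3550 genes changed (28.3% of those tested), 1702 higher and 1848 lower in FRC1, with 330 by at least 2-fold (163 higher, 167 lower). The median size of the log2 fold change among changed genes was 0.32. The 3 libraries of each group did not overlap in 44.2% of the tested genes, where chance gives 10%. Without FRC1 replicate 3 the count of changed genes was 2321, and a test against a 2-fold change left 54.

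**Figure D2:**
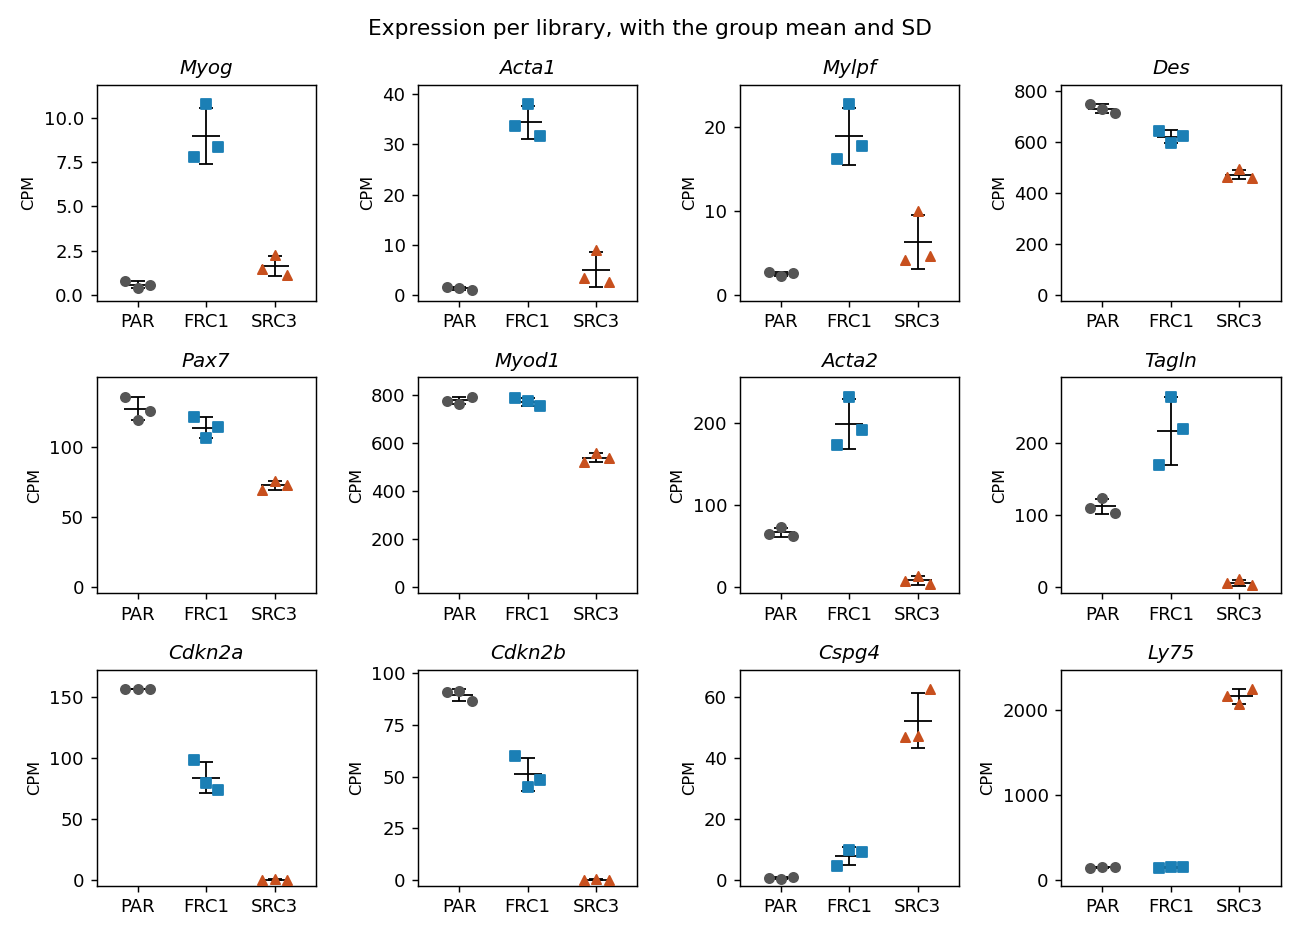
CPM of 12 named genes in each library (points), with the group mean and SD (bars); each panel has its own linear axis from 0. Myog, Acta1 and Mylpf are highest in FRC1, Cdkn2a and Cdkn2b fall from 156.5 and 89.55 CPM in PAR to 0.354 and 0.128 in SRC3, and Ly75 reaches 2155 CPM in SRC3.

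The comparison of SRC3 with PAR asked the same of reserve cells of cycle 3. Here the most prominent differences were genes near or below detection in SRC3, among them Cdkn2a and Cdkn2b, whose products restrain the cell cycle, and Myh10, a myosin gene of non-muscle cells. The smooth muscle genes Acta2 and Tagln and the imprinted genes H19 and Mest were lower as well. Hspa5, a chaperone gene of the endoplasmic reticulum, and the surface protein genes Cspg4, Ngfr and Ly75 were higher. Cdkn2a fell 433-fold to 0.354 ± 0.165 CPM (log2 fold change -8.76, SE 0.18; edgeR adjusted p = 4.9e-15), and Cdkn2b 664-fold to 0.128 ± 0.161 CPM (log2 fold change -9.37, SE 0.25; edgeR adjusted p = 5.8e-13). Of the 5 Cdkn2b reads in SRC3, 4 lay in replicate 2, without which the ratio of counts had a 95% counting interval of 430 to 94700. Ly75, which encodes an endocytic receptor (ENSMUSG00000026980, chromosome 2, 60292103 to 60383303), rose 14.7-fold from 146.7 ± 1.53 to 2155 ± 85.6 CPM (log2 fold change 3.88, SE 0.049; edgeR adjusted p = 4.5e-22). Pax7 fell 1.75-fold to 72.7 ± 3.15 CPM and Myod1 1.44-fold to 539.6 ± 18.8 CPM (edgeR adjusted p = 2.7e-09 and 6.9e-09), while Myog rose 2.75-fold to 1.615 ± 0.563 CPM (edgeR adjusted p = 0.0037).

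Several genes had no reads in any SRC3 library. Clip3 (ENSMUSG00000013921, chromosome 7, 30291728 to 30308367) had 339 counts over PAR, 8.16 ± 0.852 CPM, and was at least 108-fold lower in SRC3, against a floor of 3 counts over the group. Phactr2 (ENSMUSG00000062866, chromosome 10, 13207717 to 13474412) had 284 counts over PAR and was at least 90.9-fold lower, and the growth factor gene Hgf had 43 counts and was at least 13.8-fold lower. Myh10, the gene of non-muscle myosin IIB (chromosome 11, 68691559 to 68816632), fell 204-fold from 135.1 ± 2.72 to 0.6545 ± 0.12 CPM (log2 fold change -7.67, SE 0.11; edgeR adjusted p = 4.7e-21). Gal, the galanin gene, fell 171-fold from 18.73 ± 0.396 to 0.101 ± 0.046 CPM and Fam73a 124-fold from 16.66 ± 1.09 to 0.128 ± 0.161 CPM (counting interval 79.9 to 17700 without SRC3 replicate 2, which held 4 of its 5 reads). Brinp3 had 236 counts in PAR and 1 in SRC3, a ratio with a 95% counting interval of 40.3 to 8990, and was at least 50.5-fold lower without SRC3 replicate 3, which held that read.

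The largest rise among genes with at least 5 CPM was in Cspg4, the gene of the NG2 proteoglycan (ENSMUSG00000032911, chromosome 9, 56865033 to 56899870), 73.8-fold from 0.695 ± 0.325 to 52.31 ± 9.01 CPM (log2 fold change 6.2, SE 0.36; edgeR adjusted p = 1.3e-06). The BMP antagonist gene Grem1 rose 49.6-fold to 8.84 ± 2.52 CPM, the semaphorin receptor gene Plxna4 40.8-fold to 24.03 ± 0.441 CPM, and the mitochondrial carrier gene Slc25a29 39.5-fold to 97.62 ± 7.41 CPM. Ngfr, a neurotrophin receptor gene, rose 27.4-fold to 19.43 ± 8.09 CPM and Igf2bp3, which encodes an RNA-binding protein, 20-fold from 4.56 ± 0.301 to 91.31 ± 2.11 CPM (log2 fold change 4.32, SE 0.094; edgeR adjusted p = 4.2e-18). Pla2g7 rose 17.6-fold to 23.13 ± 3.76 CPM.

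**Figure D3:**
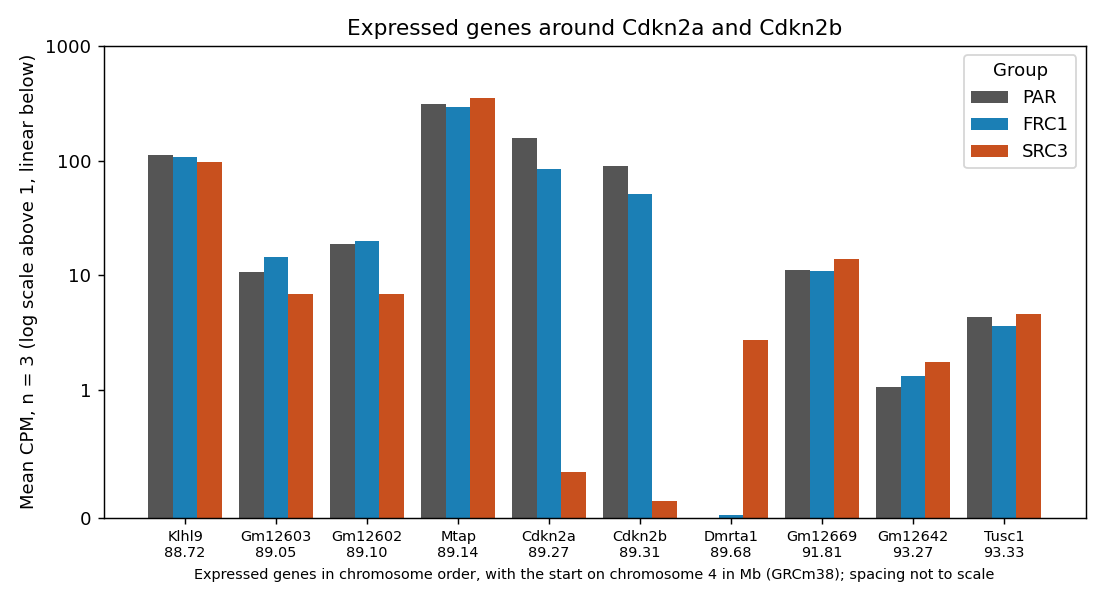
Mean CPM (n = 3) in PAR, FRC1 and SRC3 of the expressed genes around Cdkn2a and Cdkn2b on chromosome 4 in GRCm38, in chromosome order but not to scale; the axis is logarithmic above 1 CPM and linear below. Mtap, next to the pair, holds 314 CPM in PAR and 350 in SRC3, while Cdkn2a and Cdkn2b go from 156.5 and 89.55 to 0.354 and 0.128 CPM.

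Of 19 tested cell cycle inhibitors and pocket protein genes 4 rose, 7 fell and 8 did not pass, the same counts of 4 and 7 adjusted over the list alone, and the list was not called (camera adjusted p = 0.47). Btg2, an antiproliferative p53 target, fell 3.41-fold to 1.94 ± 0.559 CPM and Gadd45b rose 1.66-fold to 17.72 CPM (log2 fold change 0.73, SE 0.11). The p53 targets were called lower, with 1 of 23 up, 13 down and 9 not passing, and 1 and 13 adjusted over the list alone (camera adjusted p = 0.00039; adjusted p = 0.49 with an estimated correlation). Zmat3 fell 2.86-fold from 159.1 ± 11.6 to 55.67 ± 4.34 CPM, Ccng1 2.15-fold from 274.8 ± 9.13 to 128 ± 9.58 CPM and Eda2r 2.76-fold to 10.49 ± 0.4 CPM. Cdkn1a fell 1.16-fold to 124.8 ± 14.8 CPM (edgeR adjusted p = 0.015), a call lost without PAR replicate 2 (0.064) or SRC3 replicate 2 (0.09; range 0.00083 to 0.09). Of 40 cell cycle and mitosis genes 13 rose, 6 fell and 21 did not pass, with 13 and 7 adjusted over the list alone (camera adjusted p = 0.47, not called). The cyclin E gene Ccne1 fell 1.89-fold to 36.4 ± 2.59 CPM, while the replication genes Cdc6 and Pcna rose 1.55-fold to 80.31 ± 1.73 CPM and 1.35-fold to 160.8 ± 3.83 CPM. Mki67 stood at 311.7 ± 49.2 CPM (edgeR adjusted p = 0.098), and passed without SRC3 replicate 1 (0.00028; range 0.00028 to 0.28) and with no filter (0.0033).

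The unfolded protein and integrated stress response list was called higher, with 17 of 28 up, 1 down and 10 not passing, and 17 and 1 adjusted over the list alone (camera adjusted p = 5.5e-06; adjusted p = 0.49 with an estimated correlation). Hspa5, the gene of the chaperone BiP, rose 2.21-fold from 1978 ± 81.1 to 4369 ± 441 CPM, Manf 2.12-fold to 660.1 ± 31.3 CPM and Creld2 2.86-fold to 246.5 ± 29.5 CPM. Cytosolic ribosomal protein genes were also called higher, with 29 of 75 up, 1 down and 45 not passing (30 and 1 adjusted over the list alone; camera adjusted p = 0.00027; adjusted p = 0.78 with an estimated correlation). Rps27a rose 1.22-fold to 346.5 ± 11.2 CPM and Rps21 1.24-fold to 346.6 ± 20.7 CPM.

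Imprinted genes were called lower, with 2 of 15 up, 10 down and 3 not passing, and 2 and 12 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.49 with an estimated correlation). H19 (chromosome 7, 142575529 to 142578143) fell 7.01-fold to 150.6 ± 12.6 CPM (log2 fold change -2.81, SE 0.12; edgeR adjusted p = 2.5e-07), Mest 6.87-fold from 205.5 ± 24.7 to 29.93 ± 5.79 CPM and Plagl1 2.13-fold to 113.8 ± 22 CPM, while Ppp1r9a rose 2.57-fold to 13.99 ± 2.13 CPM. Pericyte and smooth muscle markers were called lower, with 1 of 9 up, 6 down and 2 not passing, and 1 and 7 adjusted over the list alone (camera adjusted p = 0.0071; adjusted p = 0.49 with an estimated correlation). Tagln, which encodes transgelin, fell 17.1-fold from 112.4 ± 10.7 to 6.6 ± 4.14 CPM (25.6-fold without SRC3 replicate 2) and Acta2 7.83-fold from 67.17 ± 5.64 to 8.59 ± 5.29 CPM. The member that rose was Cspg4.

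Markers of other cell types were measured beside these. Flt1, a VEGF receptor gene of endothelial cells, rose 5.86-fold from 13.42 ± 0.737 to 78.66 ± 9.5 CPM, and the other 15 endothelial markers summed to 4.66 CPM in SRC3. The summed immune cell markers held 6.97 CPM in PAR, 7.34 in FRC1 and 8.02 in SRC3. Of 7 tested glial and neural markers 5 rose, 2 fell and 0 did not pass, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.18, not called). Erbb3 rose 3.5-fold to 8.54 ± 1.55 CPM and Gap43 fell 7.27-fold to 0.202 ± 0.117 CPM. Of 8 fibroblast and fibro-adipogenic progenitor markers 4 rose, 1 fell and 3 did not pass, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.19, not called). Twist2 rose 6.43-fold to 5.64 ± 0.368 CPM, Cd34 3.75-fold to 4.29 ± 1.47 CPM and Osr1 2.28-fold to 8.76 ± 0.7 CPM.

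Satellite cell and quiescence markers moved both ways, with 8 of 22 up, 8 down and 6 not passing, and 8 and 10 adjusted over the list alone (camera adjusted p = 0.57, not called). Megf10, an engulfment receptor gene, rose 2.68-fold from 108.3 ± 9.99 to 290.4 ± 35.1 CPM, whereas the Notch target gene Hey1 fell 5-fold to 2.06 ± 0.076 CPM and Fgfr4 2.89-fold to 9.19 ± 0.683 CPM. Notch3 fell 2.6-fold to 4.4 ± 0.74 CPM (edgeR adjusted p = 0.009), a call lost without SRC3 replicate 2 (0.054; range 1.8e-07 to 0.054). Pax3 stood at 11.99 ± 0.64 CPM (edgeR adjusted p = 0.051) and Id1 at 112.1 ± 4.1 (0.073), with Id1 passing without PAR replicate 2 (0.046) or SRC3 replicate 3 (0.04; range 0.04 to 0.26). Of 36 sarcomere and contractile genes 13 rose, 8 fell and 15 did not pass, with 13 and 8 adjusted over the list alone (camera adjusted p = 0.47, not called). Myl1 rose 12-fold to 1.27 ± 0.988 CPM (6.82-fold without SRC3 replicate 2) and Sgca, a sarcoglycan gene, fell 5.82-fold to 1.43 ± 0.0403 CPM. Of 17 myogenic regulators and fusion genes 5 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.36, not called, the median log2 fold change of -0.14 and the test being opposite in sign to the mean of 0.1). Mef2c rose 7.63-fold to 3.94 ± 1.53 CPM and Tmem8c fell 4.31-fold to 1.16 ± 0.281 CPM. Myf5 had 1 read over the 3 SRC3 libraries.

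In all, 4758 genes changed between SRC3 and PAR (37.9% of those tested), 2231 higher and 2527 lower in SRC3. At least 2-fold differences were seen in 841 genes (367 higher, 474 lower) and at least 8-fold fitted differences in 40 higher and 104 lower. The groups did not overlap in 49.1% of the tested genes, where chance gives 10%. A test against a 2-fold change left 419 genes.

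The comparison of SRC3 with FRC1 set the reserve cell populations against each other. They differ in both population and cycle, which the design cannot separate. The smooth muscle genes Tagln and Acta2 and the skeletal muscle genes Myog and Actn2 were lower in SRC3. The respiratory chain gene Ndufb5, the stress response gene Trib3 and the surface protein genes Ngfr and Cd24a were higher. Tagln (chromosome 9, 45929619 to 45936058) fell 33-fold from 217.3 ± 47.1 to 6.6 ± 4.14 CPM (log2 fold change -5.05, SE 0.36; edgeR adjusted p = 6.2e-05), Acta2 23.3-fold from 199.4 ± 30.4 to 8.59 ± 5.29 CPM (log2 fold change -4.54, SE 0.33; edgeR adjusted p = 6.9e-05), and Myog 5.56-fold from 8.97 ± 1.58 to 1.615 ± 0.563 CPM (log2 fold change -2.47, SE 0.22; edgeR adjusted p = 2.9e-08). Cdkn2a and Cdkn2b were lower 232-fold and 377-fold, and without SRC3 replicate 2 the count ratio of Cdkn2b had a 95% counting interval of 244 to 53800. Myod1 fell 1.43-fold and Pax7 1.57-fold (edgeR adjusted p = 1.3e-08 and 9.2e-08).

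Of 36 sarcomere and contractile genes 1 rose, 31 fell and 4 did not pass, with 1 and 32 adjusted over the list alone (camera adjusted p = 7.3e-13; adjusted p = 0.45 with an estimated correlation). Actn2, an alpha-actinin gene, fell 14.4-fold from 3.75 ± 0.635 to 0.254 ± 0.181 CPM, the calcium channel gene Cacna1s 11.8-fold from 2.74 ± 1.1 to 0.226 ± 0.201 CPM and Myh8 9.46-fold to 0.717 ± 0.863 CPM. SRC3 replicate 2 held 22 of the 28 Myh8 reads in SRC3, and without it the folds were 28.8 for Myh8 and 23.6 for Actn2. Myh4 had 63 counts in FRC1 and 1 in SRC3, a ratio with a 95% counting interval of 10.4 to 2420, and was at least 13.6-fold lower without SRC3 replicate 2, which held that read. Of the 26 members below 5 CPM in PAR 25 fell, and their summed level went from 217 to 48.4 CPM. Of these 26 members 13 reached the count filter through FRC1, which favours a fall in SRC3. They also enter the counts and the camera result of the list. The 1 member that rose, Smyd1, a muscle methyltransferase gene named here after its value was seen, went from 3.8 ± 0.46 to 6.44 ± 0.977 CPM. Pericyte and smooth muscle markers were called lower, with 2 of 9 up, 6 down and 1 not passing, and 2 and 7 adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.56 with an estimated correlation). Mcam fell 5.76-fold to 8.89 ± 1.08 CPM and Cspg4 rose 6.63-fold from 7.82 ± 2.91 to 52.31 ± 9.01 CPM. Of 17 myogenic regulators and fusion genes 5 rose and 7 fell, or 6 and 7 adjusted over the list alone (camera adjusted p = 0.71, not called), with Mybph 6.96-fold lower (15.5-fold without SRC3 replicate 2) and Jph2, a junctophilin gene, 1.84-fold lower at 157.1 ± 15.2 CPM.

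Of 42 nuclear genes of oxidative phosphorylation 24 rose, 0 fell and 18 did not pass, with 26 and 0 adjusted over the list alone (camera adjusted p = 1.4e-06; adjusted p = 0.56 with an estimated correlation). The sizes were small, as in Ndufb5, 1.24-fold to 108.7 ± 1.33 CPM, and Ndufs1, 1.21-fold to 247.6 ± 11.1 CPM. Of 10 mitochondrially encoded genes 6 rose, 0 fell and 4 did not pass, with 6 and 0 adjusted over the list alone (camera adjusted p = 0.002; adjusted p = 0.78 with an estimated correlation). Among them mt-Cytb rose 1.52-fold from 2615 ± 111 to 3969 ± 269 CPM and mt-Nd5 1.57-fold to 1590 ± 191 CPM. Neither list was called in SRC3 against PAR. There 5 nuclear genes rose, 3 fell and 34 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.39). Of the mitochondrially encoded genes 2 rose, 0 fell and 8 did not pass (camera adjusted p = 0.48). Both lists had been called lower in FRC1 against PAR. The unfolded protein and integrated stress response was called higher again, with 14 of 28 up, 3 down and 11 not passing, and 17 and 3 adjusted over the list alone (camera adjusted p = 0.002; adjusted p = 0.85 with an estimated correlation). Vldlr rose 4.53-fold from 13.36 ± 0.235 to 60.5 ± 3.86 CPM, the cystine transporter gene Slc7a11 2.26-fold to 93.57 ± 14.3 CPM and the pseudokinase gene Trib3 2.18-fold to 131.1 ± 18.7 CPM.

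The largest differences by the naming rule included Platr3, a long non-coding RNA gene (ENSMUSG00000084762, chromosome 2, 135648907 to 135652063), which had 485 counts in FRC1 and 0 in SRC3 and was at least 155-fold lower. Clip3 and Phactr2 were at least 108-fold and 80.8-fold lower, and Myh10 fell 164-fold from 108.7 ± 6.19 CPM. In the other direction Ngfr rose from 0.126 ± 0.219 to 19.43 ± 8.09 CPM, a fitted 150-fold that rests on 5 reads in FRC1 replicate 1, without which it was at least 184-fold higher. Also higher were Cd24a, a surface glycoprotein gene, 37.6-fold from 2.02 ± 0.548 to 76.44 ± 14.8 CPM, and Gpnmb 19.8-fold to 17.82 ± 3.69 CPM. Nptx1, a pentraxin gene, rose 13.4-fold from 9.9 ± 0.152 to 132.9 ± 10.6 CPM (log2 fold change 3.75, SE 0.076; edgeR adjusted p = 1.5e-18), and Ly75 14.6-fold. Flt1 rose 8.49-fold. Cdkn1a rose 1.2-fold (edgeR adjusted p = 0.0064), Cd34 2.36-fold (0.00058), and Id1 fell 1.17-fold (0.0028). Pax3 (edgeR adjusted p = 0.37) did not pass, nor did Mki67 (0.22) or Notch3 (0.06), but Mki67 did without SRC3 replicate 1 (0.0015; range 0.0015 to 0.56) and with no filter (0.036). Notch3 passed without FRC1 replicate 2 (0.013) or FRC1 replicate 3 (0.036; range 0.013 to 0.19), with no filter (0.005) and with DESeq2 (adjusted p = 0.036).

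In all, 4199 genes changed between SRC3 and FRC1 (33.5% of those tested), 1940 higher and 2259 lower in SRC3, with 819 by at least 2-fold (351 higher, 468 lower). The groups did not overlap in 42.8% of the tested genes, where chance gives 10%, and a test against a 2-fold change left 415 genes.

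**Figure D4:**
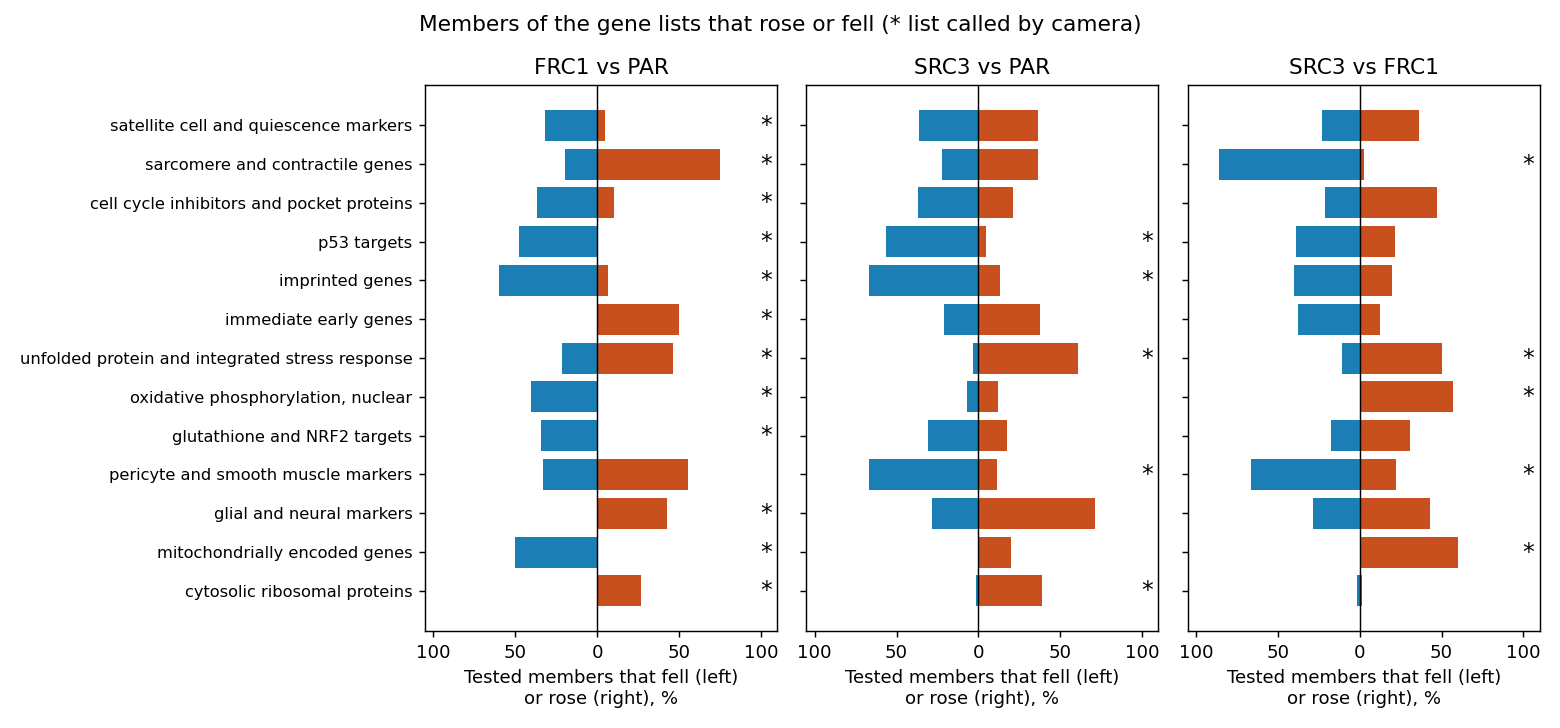
Percent of the tested members of 13 gene lists that fell (bars to the left) or rose (bars to the right) in each comparison, by edgeR adjusted p; a star marks a list called by camera with a preset correlation. Sarcomere and contractile genes rose in 27 of 36 members in FRC1 against PAR and fell in 31 of 36 in SRC3 against FRC1.

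The reserve cell populations shared part of their differences from PAR. In both, 804 genes were higher and 994 lower, where independent lists of these sizes would share 303 and 372. The shared falls included Cdkn2a, Cdkn2b, Vcam1, Zmat3, Eda2r, H19 and Ppargc1a, and the shared rises Cspg4, Creld2, Sdf2l1, Myog and Mef2c. Opposite calls were made for 116 genes higher in FRC1 and lower in SRC3, among them Acta2, Tagln and Igf2, and for 152 genes lower in FRC1 and higher in SRC3, among them Flt1, Vldlr and Cd24a, where independent lists would give 343 and 329. Across the 12540 genes the log2 fold changes against PAR had a Pearson correlation of 0.366. In 20 simulations all 9 libraries were drawn at the PAR levels, so that unchanged groups shared simulated PAR libraries. These gave 0.502 on average and 0.544 at most. Only noise and the shared controls set that value, so it is no yardstick for the 0.366 of groups that changed. The covariance was 0.129, against 0.0176 in the simulations, a difference of 0.111. The simulated groups shared 0.05 called genes on average. Part of the excess of shared calls over independent lists can come from the shared PAR libraries, which were not split between the comparisons.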

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

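The tests of sequencing depth, library size, the count filter, differentiated muscle cells, pericytes, endothelial cells and glial cells were chosen only after the result was seen.

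Cdkn2a and Cdkn2b were nearly absent in SRC3, with 14 and 5 reads against 6481 and 3707 in PAR. A lower depth is argued against by the unscaled gene counts, whose mean in SRC3 was 0.953 times that in PAR. A loss of DNA reaching to the next expressed gene is argued against by Mtap (log2 fold change 0.15, 95% interval 0.04 to 0.27). Beyond Mtap, Gm12602 and Gm12603 had log2 fold changes of -1.45 and -0.65. On the other side Dmrta1 had 108 reads in SRC3 and 0 in PAR. It counted as expressed only through SRC3 and could not have fallen, so only the presence of its reads argues against a loss. The 23 genes below 5% of their PAR level in SRC3 held 0 neighbouring pairs other than Cdkn2a and Cdkn2b, against 0.0399 on average in 10000 random sets. This argues against a series of deletions spanning several expressed genes. A deletion of Cdkn2a and Cdkn2b alone, or silencing of both, may account for the pattern as a hypothesis, and reads that could tell them apart were not analysed here.

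The 26 sarcomere genes below 5 CPM in PAR were higher in FRC1 than in PAR, and 25 of them were lower in SRC3 than in FRC1. They did not all return to the PAR level: against PAR, 12 of the 26 were higher in SRC3 and 0 lower. Their summed level was 21.1 CPM in PAR, 217 in FRC1 and 48.4 in SRC3. Library size is argued against by a ratio of mean sizes of 0.996 between FRC1 and PAR. A small share of differentiated muscle cells may have carried these transcripts; 100% of the genes had a positive log2 fold change, but 13 of them reached the count filter through FRC1 (all 34 low-level list members with a read, unfiltered, had more reads in FRC1 than in PAR). A rise of the fusion genes was also looked for as a sign of such cells, but Tmem8c and Gm7325 had log2 fold changes of -0.5 and -0.7. Neither change passed the edgeR threshold, so these genes leave the question open. A small share of such cells and a low level in all cells cannot be told apart in bulk RNA, and the difference between the populations named by the design remains open and untested.

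Cspg4, Ngfr and Flt1, markers of pericytes, glial cells and endothelial cells, were higher in SRC3 than in PAR. Pericytes or smooth muscle cells were examined through Acta2 and Tagln, which fell (the higher log2 fold change was -2.97). PAR itself expressed both genes, so their fall cannot tell whether a small share of such cells was present. Endothelial cells are argued against by the 15 other listed markers, which summed to 4.66 CPM beside 78.7 for Flt1. Of 6 other glial markers 1 reached 1 CPM, and Sox10, S100b and Foxd3 had 0 reads. These 6 were part of a longer glial and neural list that also held Erbb3, which rose in SRC3. Of its 7 tested members 5 rose and 2 fell, so the 6 alone do not settle whether glial cells were present. A change of expression in the SRC3 cells themselves is a candidate explanation, put forward as a hypothesis, that no test addressed.

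Some genes moved against PAR in opposite directions in the reserve populations: 116 were higher in FRC1 and lower in SRC3, and 152 the reverse. The difference between SRC3 and FRC1 passed for each. Choosing genes by opposite calls against the same PAR libraries nearly fixes that outcome, so it is no separate support. Among named genes of the first kind, the log2 fold change of SRC3 against FRC1 was -5.05 for Tagln, -4.54 for Acta2, -3.78 for Igf2, -2.53 for Mcam, -2.41 for Nr4a2, -2.02 for Tnc and -1.85 for Mmp2. It was -1.7 for Cdh10, -1.48 for Dusp1, -0.94 for Mkx, -0.84 for Vegfa and -0.75 for Egr1. Brinp3, with 1 read in SRC3, had a fitted value of -7.93, and Platr3, with 0 reads, of -10.31, neither of which is a bound; the 1 read of Brinp3 lay in SRC3 replicate 3, without which it was at least 73.9-fold lower. Among genes of the second kind it was 5.23 for Cd24a, 4.31 for Gpnmb, 3.75 for Nptx1, 3.3 for Sapcd1 and 3.09 for Flt1. It was 2.94 for Amigo2 (whose value in FRC1 against PAR moved from -1.76 to -2.41 without FRC1 replicate 1) and 2.18 for Vldlr. Smaller values were 1.89 for Slc16a3, 1.72 for Sfrp1, 1.18 for Slc7a11, 0.65 for H2-D1, 0.62 for B2m, 0.6 for mt-Cytb, 0.51 for mt-Nd4, 0.46 for Rbpj and 0.34 for Mcm6. Some of the calls against PAR behind these values were lost with 1 library left out, with edgeR adjusted p up to 0.13 for Sfrp1 in FRC1 (lost without PAR replicates 2 and 3 and each FRC1 replicate; range 0.032 to 0.13; no filter 0.066, DESeq2 0.1) and 0.065 for Slc7a11 in FRC1 (PAR replicates 1 and 3, FRC1 replicate 3; range 0.0016 to 0.065). The same held for mt-Nd4 in SRC3 (PAR replicates 2 and 3, SRC3 replicate 3; range 0.0014 to 0.073) and for Mkx in FRC1 (PAR replicates 1 and 3, each FRC1 replicate; range 0.019 to 0.14; DESeq2 0.1) and in SRC3 (each PAR replicate, SRC3 replicates 1 and 2; range 0.0034 to 0.16; DESeq2 0.071).

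Reads outside the gene counts were more frequent in the reserve populations. Reads that did not align numbered 20.47 per 100 gene counts in FRC1 and 26.02 in SRC3, against 19.15 in PAR (highest PAR library 19.5). Alignments that were not unique numbered 127.9 and 143.9 per 100 gene counts, against 118.5 in PAR (highest 120.3). An exact permutation test gave p = 0.1 for each, the smallest possible with 3 against 3.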

How the results depend on the processing

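None of the alternatives was added after the result was seen. The tests against a 2-fold change left 54 genes in FRC1 against PAR, 419 in SRC3 against PAR and 415 in SRC3 against FRC1, fewer by construction. Leaving out 1 library at a time gave 2321 (without FRC1 replicate 3; the cause was not tested) to 3966, 3838 to 4877 and 3338 to 4254 genes. DESeq2 gave 2928, 4104 and 3602 genes, a stricter filter 3304, 4164 and 3622, and no filter 3693, 4964 and 4387. With a correlation estimated per list 0, 0 and 0 lists were called. For the called lists the estimates lay above the preset 0.01, except for glial and neural markers (-0.0074). They were 0.17 for sarcomere genes, 0.34 for the unfolded protein list, 0.47 for ribosomal proteins and 0.52 for mitochondrially encoded genes. A higher correlation makes camera stricter, so the calls rest on the preset. Other causes of the lost calls were not tested. Fry, which does not compare a list with other genes, called 16, 15 and 17, and 11 to 13, 5 to 6 and 5 to 7 were called with 1 library left out. The value of Myod1, FRC1 vs PAR, not past the threshold, ranged from -0.0243 to 0.0051 in log2 fold change and changed sign without PAR replicate 3 (0.0047) and FRC1 replicate 3 (0.0051); the cause was not tested. Of 405 named gene results, 385 kept direction and side of the threshold under DESeq2, 401 under voom, 405 with library sizes alone, 404 with RLE and 379 to 394 with 1 library left out. The correlation of the changes against PAR ranged from 0.328 to 0.393 with 1 library left out. Using replicate numbers as a block gave 3560, 4798 and 4221 genes and 13, 5 and 6 lists. With the block Mki67 passed in SRC3 against PAR (edgeR adjusted p = 0.0055) and FRC1 (0.033), and Notch3 in SRC3 against FRC1 (0.013). Slc7a11 in FRC1 against PAR no longer passed (edgeR adjusted p = 0.056). The deviations of libraries sharing a number correlated at -0.07 to 0.12, with the own number as best partner in 14 of 18 cases. A random pick among 3 candidates would give fewer such cases on average, but the 18 are not independent, as each pair is counted from both sides. Same-number correlations were 0.022 to 0.12 between PAR and the other groups, but 0.032, -0.055 and -0.07 between FRC1 and SRC3. The share of reads in no gene also rose with the replicate number in every group. The numbers may therefore link libraries across groups, which was not tested and which the main fit leaves out. The depth leaves genes under about 0.21 to 0.231 CPM at 3 counts or fewer in a library.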

Other observations

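The largest chromosome median differences and the splits of libraries were tested as planned, and the gene groups in this part were fixed before their values were seen, so none of these tests was chosen only after the result was seen.

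Hox genes, which encode positional identity along the body axis, moved in both directions in SRC3. Of 24 tested, 7 rose and 5 fell in SRC3 against PAR, also adjusted over the list alone (camera adjusted p = 0.58, not called; median log2 fold change 0.02 and mean -0.03). Hoxb9 fell 18.7-fold from 10.08 ± 0.959 to 0.532 ± 0.433 CPM (edgeR adjusted p = 1.8e-10; 32.7-fold without SRC3 replicate 2) and stood at 3.23 ± 0.324 CPM in FRC1, while Hoxb6 rose 2.11-fold to 14.52 ± 1.75 CPM. Of 20 Wnt pathway genes 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.65, not called; median -0.00488, mean 0.13). Wnt10b rose 5.52-fold from 2.46 ± 0.205 to 13.64 ± 2.71 CPM, and Wnt5a had 3 counts in SRC3 and 56 in PAR, a ratio with a counting interval of 5.82 to 89.5 (6.24 to 1460 without SRC3 replicate 2). Of 19 BMP pathway and Id genes 5 rose and 6 fell, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.59, not called). The receptor gene Bmpr1b fell 19.2-fold from 2.57 ± 0.507 to 0.126 ± 0.0432 CPM and the antagonist gene Fst 2.76-fold from 12.25 ± 1.97 to 4.42 ± 0.609 CPM.

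Genes of the extracellular matrix were lower in SRC3 in more members than they were higher. Of 33 collagen and structural matrix genes 8 rose and 19 fell in SRC3 against FRC1, or 8 and 20 adjusted over the list alone (camera adjusted p = 0.057, not called; adjusted p = 0.85 with an estimated correlation). The basement membrane gene Nid2 fell 4.16-fold from 13.99 ± 2.73 to 3.34 ± 0.875 CPM and the fibrillin gene Fbn1 4.26-fold from 43.09 ± 2.61 to 10.13 ± 0.925 CPM. In the same list the matrix gene Tnc was 4.05-fold lower at 370.5 ± 92.5 CPM. Of 28 matrix remodelling genes 6 rose and 14 fell, or 8 and 14 adjusted over the list alone (camera adjusted p = 0.3, not called). Among them the gelatinase gene Mmp2 was 3.59-fold lower at 35.92 ± 4.4 CPM. Of 19 interferon-stimulated genes 7 rose and 2 fell in SRC3 against FRC1, also adjusted over the list alone (camera adjusted p = 0.16, not called), with Bst2 1.8-fold higher at 20.17 ± 2.54 CPM.

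No chromosome stood out in its median log2 fold change. The largest difference between a chromosome and the other genes was -0.0468, on the X chromosome with 435 genes in FRC1 against PAR, which argues against a whole chromosome gained or lost in most cells. Xist, the RNA of the inactive X chromosome, was present in every group at 643 CPM in PAR, 723 in FRC1 and 1040 in SRC3.

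The real groups gave 3550 changed genes in FRC1 against PAR, 4758 in SRC3 against PAR and 4199 in SRC3 against FRC1, and the highest of the 9 other splits of each 6 libraries gave 0. In each comparison 1 of 10 splits gave as many genes, the real one, and 10 splits are too few for a share under 0.05.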
